A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

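The series measured transcript levels of Saccharomyces cerevisiae BY4741 MATa cells with spotted 2-colour arrays. Per the labels, cultures in rich medium were given 10 µM of Iztli peptide 1 (IP-1) or left without it, and were harvested after 3.5, 7, 15 or 30 min. Total RNA was extracted with Trizol and copied into cDNA with Cy3 for untreated and Cy5 for treated cells. Per the series design text, 4 control and 4 treated cultures were grown and harvested independently. Each array thus held 1 pair of cultures, and no array had the dyes swapped. The 8 GEO samples are the 2 spots of each gene on 4 arrays, so replicates 1 and 2 of an exposure are technical and were counted as 1. All p-values rest on the spread between 4 arrays of different exposures, which holds differences of time, culture, labelling and hybridisation together.

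The deposited scanner tables give 1 line per spot. Per the file headers, they hold the mean raw intensity, the mean and SD of the local background intensity, and a net intensity for the control and the peptide channel. The scanner software is not given in the sources used here. The net intensity of the untreated channel equals raw minus background, while that of the treated channel is also rescaled with brightness, as the deposited values themselves show. The deposited series matrix holds log10 of raw Cy5 over raw Cy3 intensity for each spot, with no background subtraction and no centring, which was read from the values, since they equal the scanner files' ratios within 4.98e-07. Direction and scale of that matrix are thereby known. Its column medians were −0.0440 and −0.0446 at 3.5 min, −0.216 and −0.222 at 7 min, −0.0127 and −0.0137 at 15 min, and −0.0302 and −0.0292 at 30 min, on the log10 scale. On the log2 scale the raw ratios had medians of −0.15, −0.73, −0.04 and −0.10 in the order of the exposures, so values that are not centred carry these shifts.

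The main analysis started from the raw and background intensities. Background was corrected with normexp and an offset of 50, which draws the ratios of dim spots toward 0. Each array was normalised with global loess (span 0.3, 4 iterations), with weight 0 for control and empty spots, so ratios are relative to genes of equal brightness on the array. Duplicate spots were averaged. A gene was tested if both of its spots exceeded the local background by more than 2 background SDs in at least 1 channel on all 4 arrays, which kept 6152 of 6336 features. This filter is lenient, since 68.1% to 88.8% of the 320 empty spots passed the same limit in a channel. In both channels of all arrays 5816 features passed, and 5026 exceeded the upper limit of the empty spots. At 30 min, 3 spots in Cy3 and 4 in Cy5 were saturated and were kept. Gene names are those of the deposited tables, updated through locus tags of the R64 reference table, to which 5763 features matched and 573 did not. A further 275 features carry names of several genes, and 86 carry the suffix -r, whose meaning is not given in the sources used here. No genome build is named for the probes and their sequences were not used here, so no coordinates are given. The 32 features named after Arabidopsis genes stayed out of all tests of yeast genes.

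R 4.3.3 with limma 3.58.1 computed the statistics, and Python 3.11.15 with matplotlib 3.10.9 drew the figures. The mean log2 ratio over the 4 arrays was tested against 0 with lmFit and eBayes (two-sided, Benjamini-Hochberg, adjusted p under 0.05), and the trend with exposure as the slope on log2 of minutes in the same way. The prior had 5.32 degrees of freedom for the mean. Single exposures were described without a test, as genes whose spots both had a log2 ratio of at least 1 in size. No gene had spots past this limit in opposite directions (0 on each array). For 31 gene lists, camera with a preset correlation of 0.01, camera with an estimated correlation and fry were run. The median of each list on each array was placed among 10000 random lists of the same size drawn from 10 brightness bins. A call in a list is also given adjusted over the list alone. In 200 simulated genes with a log2 change of 0.5 among 6152, the test of the mean recovered 155 with 7 false calls. For the slope test the simulated change was 0.5 per doubling of the exposure, which adds up to more over the whole series. It recovered 158 of 200 with 3 false calls. With 1 in place of 0.5, the test of the mean recovered 194 with 3 false calls and the slope test 195 with 5. Smaller trends were not simulated, so the recovery of such trends by the slope test is not known. For the lists, camera with the preset correlation recovered 1 of 1 list shifted by 0.3, with 0 false calls. The simulated genes varied independently, had no dye effect, and each had the same spread on every array. These counts therefore do not cover correlated genes, dye effects or arrays of unequal spread.

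The lists cover the pheromone response, a-specific and alpha-specific genes, meiosis, the genes deleted in the strain, cell cycle stages, histones, ribosomal proteins and ribosome biogenesis, stress responses, cell wall and calcineurin targets, membrane lipids and drug efflux, carbon use and respiration, mitochondrial ribosomal proteins, the proteasome, amino acid, sulfur, phosphate and iron metabolism, hexose transport and galactose use, and filamentous growth. The lists, the tests and the rule for naming genes were fixed before the data were examined. The rule took the 12 highest and 12 lowest genes called on the mean with 1 sign on all arrays, up to 6 genes in each direction per exposure above background in both channels, the 5 smallest p in each direction of the slope where none passed, 2 or 3 members per list, and a fixed set of mating and deleted genes. Every member of a list that passed is named, which goes beyond the 2 or 3 of the rule, and other genes outside the rule are named as such. Alternatives fixed at the same time were no background correction, plain subtraction, median centring, print-tip loess over 32 blocks, other filters, the series matrix, each array or spot left out, duplicate spots kept, the spot number as a block, an intensity trend in the prior, other forms of the slope and other fold limits. The empty-spot limit, the authors' net intensities, the centred series matrix and the order of times by column number were chosen after seeing the data.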

Results

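Haploid Saccharomyces cerevisiae cells of mating type a (strain BY4741) were exposed in rich medium to 10 µM Iztli peptide 1 (IP-1), a designed antimicrobial peptide that carries the sequence of the alpha mating pheromone, or were left untreated. RNA was taken after 3.5, 7, 15 and 30 min. Each exposure had 1 treated and 1 untreated culture, so that 4 treated and 4 untreated cultures entered the study. The treated RNA (Cy5) and the untreated RNA (Cy3) of an exposure were hybridised together to 1 spotted array of yeast open reading frames. Each gene was spotted side by side as 2 spots, which GEO lists as replicates 1 and 2. These spots measured the same labelled RNA and were averaged, which left 1 independent ratio per exposure and 4 in all. All ratios are log2 of IP-1 over untreated.

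Of 6336 gene features, 6152 were tested. The median Cy3 signal was 3.74, 2.43, 3.84 and 2.55 times its local background on the 3.5, 7, 15 and 30 min arrays, and the median Cy5 signal was 2.50, 3.18, 3.77 and 1.86 times its own. The log2 ratios of the duplicate spots correlated across genes at 0.778, 0.761, 0.908 and 0.559 in the same order, with a spot SD of 0.12, 0.11, 0.11 and 0.14. The ratios of all genes had an SD of 0.25, 0.22, 0.35 and 0.18. The 15 min array therefore had the widest ratios and the best match between spots, and the 30 min array the narrowest and the poorest. The number of arrays limits the precision of every mean.

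The comparison of treated with untreated cells over all exposures asked which transcripts responded to the peptide. Of the 12 highest called genes, 4 belonged to the mating lists (AGA1, KAR4, MFA1 and SST2). AGA1 (YNR044W), which encodes the anchorage subunit of a-agglutinin on the surface of mating cells, rose most, with a mean log2 ratio of 1.95 ± 0.52 (SD, n = 4; 3.88-fold; limma, adjusted p = 0.0024), and it was higher on 4 of 4 arrays at 2.68, 1.65, 1.97 and 1.51. The rise extended to KAR4, a transcription factor of the mating programme (1.06 ± 0.68, SD), to MFA1, which encodes a-factor (0.98 ± 0.77, SD), and to SST2, which desensitises cells to pheromone (0.92 ± 0.36, SD). Adjusted p was 0.024 for KAR4, 0.042 for MFA1 and 0.0081 for SST2. The calls of KAR4, MFA1 and SST2 ended without the 3.5 min array, at adjusted p of 0.127, 0.191 and 0.089, and those of KAR4 and MFA1 without the 7 min array, at 0.087 and 0.085. These 2 fits called only 12 and 10 genes in all, so such losses alone do not show that a rise came from the array left out. At 7 min KAR4 was at 0.57 and MFA1 at 0.22, below their means over the 4 arrays. Cy5 marked the treated RNA on every array, so a dye effect of a probe that is constant across arrays is part of each mean.

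Among 33 tested genes of the pheromone response, 6 rose (AGA1, KAR4, SST2, FIG2, MID2 and FUS2) and 1 fell, PRM10 at −0.51. Adjusted over the list alone, 9 rose and 1 fell. Of the 7 a-specific genes, which are transcribed in a cells and not in alpha cells, MFA1 and MFA2 rose. Adjusted over the list alone, 6 rose and 0 fell. Both lists stood above the other genes in limma's camera test with a preset correlation, each at adjusted p = 0.0025. Neither was called in camera with an estimated correlation (adjusted p = 0.89) or by the fry test (adjusted p = 0.23 for both). Each was called in 17 of 19 other settings, all of which kept the preset correlation. Several classical pheromone targets had large ratios at some exposures only and did not pass. FUS1, needed for cell fusion, was at 1.17, −0.10, 0.68 and 0.18 after 3.5, 7, 15 and 30 min (adjusted p = 0.13). BAR1, the protease that degrades alpha-factor, was at 1.19, −0.17, 1.12 and 0.40 (adjusted p = 0.088). PRM1, a membrane protein of mating cells, was at 1.22, −0.08, 2.18 and 0.06 (adjusted p = 0.14).

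The receptor gene STE2 was at 0.47, −0.13, 0.35 and 0.15, FIG1 at 0.36, −0.20, 0.87 and −0.05, and FAR1, which arrests the cycle in response to pheromone, at 0.21, 0.11, 0.11 and 0.24. The means of STE2 and FAR1 lay above 0 after loess and below 0 in the deposited log ratios, which are not centred, at −0.17 and −0.12. STE12, the transcription factor of the pathway, was at 0.01, −0.24, −0.57 and −0.15. None of these genes passed. The alpha-specific genes, markers of the opposite mating type, had 0 risen and 0 fallen of 6 tested, also adjusted over the list alone, and STE3, the a-factor receptor among them, was at −0.24, −0.03, −0.28 and 0.10. The 4 genes deleted in this strain had 0 risen and 0 fallen, also adjusted over the list alone, and their means were −0.06 for URA3, −0.04 for LEU2, 0.05 for MET17 and −0.01 for HIS3. The mean of LEU2 was 0.15 after median centring, that of MET17 was −0.09 in the deposited log ratios, and those of URA3 and HIS3 also changed sign between settings. The LEU2 feature was among the brightest on every array, at a percentile of 99.9 for its mean brightness.

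**Figure D1:**
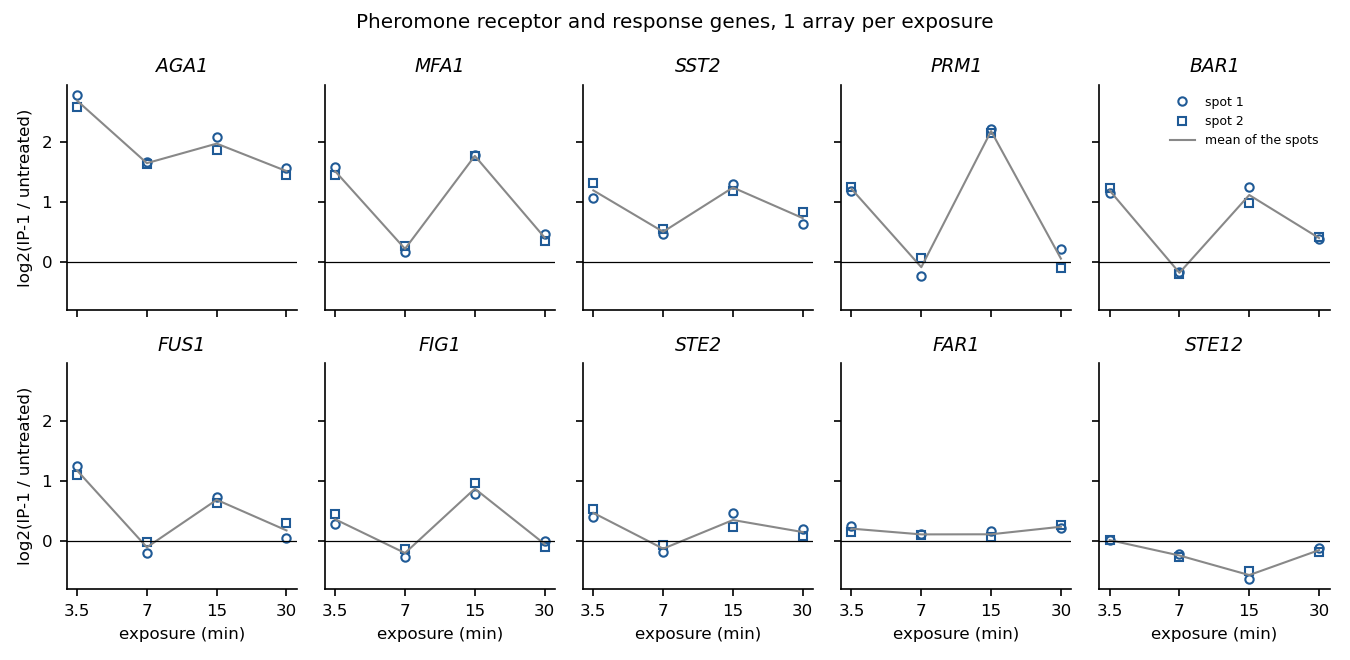
Log2 ratio of IP-1 over untreated RNA for 10 genes of the pheromone receptor and response, by exposure in min, with both spots of the 1 array per exposure as points and their mean as a line (axis not to scale in time). AGA1 was above 1.5 at every exposure, while PRM1 went from 1.22 at 3.5 min to −0.08 at 7 min and 2.18 at 15 min.

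Across all genes, 548 changed on the mean of the exposures (limma, Benjamini-Hochberg), with 128 higher and 420 lower, and each had the same sign on all 4 arrays. Most of these changes were small, with a median size of 0.38, and 6 genes were at least 2-fold higher on average and 1 at least 2-fold lower. Outside the mating lists, the genes that rose most were MRPL25, a mitochondrial ribosomal protein (2.84-fold, with a log2 SD of 0.37, n = 4), the open reading frame YMR304C-A (log2 1.23 ± 0.55), RPO21, the largest subunit of RNA polymerase II (1.12 ± 0.34), and FIT2, a cell wall mannoprotein that helps retain siderophore iron (1.11 ± 0.16). LOC1, a nucleolar protein of ribosome assembly (0.98), DAN1, a cell wall mannoprotein (0.97), TAX4 (0.92) and SUT1, a transcription factor of sterol uptake (0.86), followed.

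The gene that fell most was SBH1, a subunit of the Sec61 translocation channel, at −1.11 ± 0.21 (SD, n = 4; 2.16-fold lower; adjusted p = 0.0019). PFK27, which makes fructose 2,6-bisphosphate, fell as well, at −0.88, −0.98, −1.10 and −1.02 on the 4 arrays. YNL120C was at −0.92, PEX6, a peroxisome assembly factor, at −0.88, FAL1, a nucleolar helicase, at −0.84, and CSE1, the export receptor of importin alpha, at −0.80. MET30, an F-box protein, was also at −0.80, RSC9, a chromatin remodeller subunit, at −0.78, the phospholipase PLB1 at −0.77 and the mitochondrial ADP/ATP carrier AAC1 at −0.73. The features for FEX2 (−0.73) and YGR254W-R (−0.74), the latter bearing the locus name of the enolase gene ENO1 with a suffix -r, carry the names of several genes and can bind more than 1 transcript.

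The count of 548 fell most when the 3.5 or the 7 min array was left out. It was 12 without the 3.5 min array and 10 without the 7 min array, against 467 without 15 min and 575 without 30 min. Before adjustment, 1411, 1184, 1415 and 1740 genes had a limma p under 0.05 without the 3.5, 7, 15 and 30 min array. The fall to 12 and 10 alone therefore does not show that the changes came from those arrays. Of the 12 highest and 12 lowest called genes, 10 kept their call without the 3.5 min array and 9 without the 7 min array. AGA1, MRPL25, RPO21, FIT2, TAX4, SBH1 and PFK27 were called with any 1 array left out. A separate fit of the same model held the tested yeast features and 32 control features named after Arabidopsis genes, the latter without the background filter. Of the 32, 14 were called, each of them lower, against 9.05% of the yeast features.

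**Figure D2:**
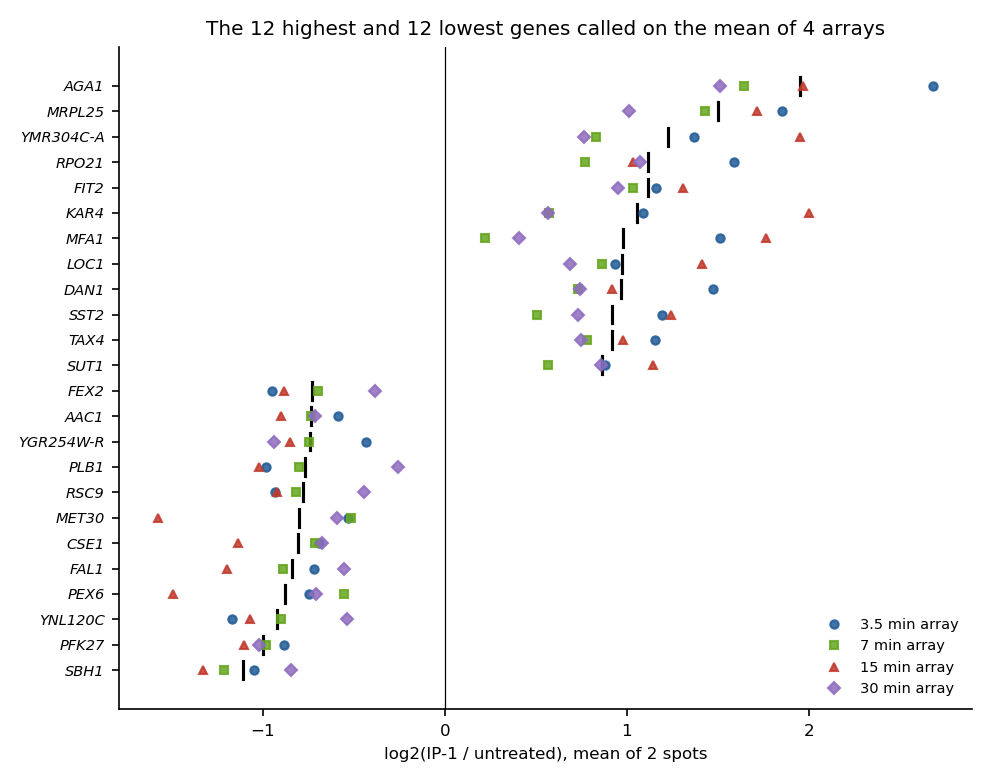
Log2 ratio of IP-1 over untreated RNA on each of the 4 arrays (coloured points) and their mean (black bar) for the 12 highest and 12 lowest genes among those called. The same sign on 4 of 4 arrays was a condition for choosing these 24 genes, and their means ran from 1.95 for AGA1 to −1.11 for SBH1.

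Over all 6152 tested genes, 548 were called, 128 higher and 420 lower. The list counts here and below are to be read against that share, and a count near it does not set a list apart. Genes of translation and central carbon use were called in part. Of 50 cytosolic ribosomal proteins and ribosome-bound factors, 3 rose (STM1 at 0.39, RPP0 at 0.36 and RPS19A at 0.35) and 2 fell (RPL16A at −0.31 and RPS22A at −0.38), and the counts were equal adjusted over the list alone. As a group they stood above the other genes in camera with a preset correlation (adjusted p = 0.021) and not with an estimated one (adjusted p = 0.89). The fry test, which asks whether the list itself moved in 1 direction, gave an adjusted p of 0.53. The camera call ended without the 3.5 min array (adjusted p = 0.32) and without the 15 min array (adjusted p = 0.54), in a range of 9.8e-06 to 0.89 over the settings tried. Of 20 glycolytic and fermentation genes, 4 rose, CDC19 at 0.56, TDH3 at 0.51, PDC1 at 0.45 and TDH1 at 0.40. ENO1 at −0.53 and PGI1 at −0.33 fell, and adjusted over the list alone 5 rose and 2 fell. RPS19A, RPL16A, RPS22A, TDH3 and ENO1 have near-identical or closely similar relatives to which a probe can bind.

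Of 20 genes of hexose transport and galactose use, 0 rose and 5 fell, GAL7 at −0.71, HXT2 at −0.66, GAL1 at −0.52, HXT4 at −0.41 and HXT5 at −0.39. Adjusted over the list alone, 2 rose and 6 fell. A feature with the HXT2 locus name and the suffix -r was at −0.03 against −0.66 here. The list was not called against the other genes in camera (adjusted p = 0.39), nor in fry for a move of its own in 1 direction (adjusted p = 0.094). Of 41 genes of the TCA cycle and respiratory chain, 0 rose and 2 fell, SDH3 at −0.65 and CIT1 at −0.50, as adjusted over the list alone. Of 60 mitochondrial ribosomal proteins, MRPL25 rose and MRPS9 fell (−0.45), as adjusted over the list alone. In the iron regulon, 2 of 25 genes rose (FIT2 and FIT1 at 0.41) and FIT3 fell at −0.27, with the same counts adjusted over the list alone.

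Lists of stress and of the cell surface were compared in the same way. Of 40 general stress genes, 0 rose and 0 fell, also adjusted over the list alone. The list's median was 0.04 and its mean −0.01. Of 26 heat shock chaperones, SSE1 rose (0.39) and SSC1 (−0.37), CPR6 (−0.26) and HSP30 (−0.26) fell, and adjusted over the list alone 3 rose and 3 fell. Of 18 genes of the unfolded protein response, SEC61 rose (0.38) and MPD1 fell (−0.26), with 2 risen and 1 fallen adjusted over the list alone. Of 33 cell wall integrity genes, MID2 rose (0.49) and GAS1 (−0.60) and PST1 (−0.52) fell, with 5 risen and 4 fallen adjusted over the list alone. Of 19 calcineurin targets, the calcium pump gene PMC1 rose (0.31) and GYP7 fell (−0.26), with 4 risen and 1 fallen adjusted over the list alone. Of 23 osmotic stress genes, PTP3 (−0.55) and HXT5 fell, and of 28 oxidative stress genes the efflux pump FLR1 fell (−0.31). These 2 lists had equal counts adjusted over the list alone, with 0 risen in each.

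Among lists of membrane lipids and drug efflux, 2 of 25 ergosterol genes fell (ERG4 at −0.46 and ERG25 at −0.25; 1 adjusted over the list alone), and 1 of 25 phospholipid and fatty acid genes fell, the desaturase OLE1 at −0.31 (1 adjusted over the list alone). Of 14 genes of drug efflux, 3 fell, YOR1 at −0.38, PDR10 at −0.34 and PDR16 at −0.32 (3 adjusted over the list alone). In these 3 lists 0 genes rose. Amino acid synthesis had 1 of 42 risen (GLN1, 0.33) and 1 fallen (HIS4, −0.30), as adjusted over the list alone, and sulfur amino acid synthesis had 1 of 20 risen (MET6, 0.28), with 0 adjusted over the list alone. Of 49 ribosome biogenesis genes, NOP2 rose (0.37) and BRX1 (−0.52) and IPI3 (−0.43) fell, as adjusted over the list alone.

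In the cell cycle lists, POL2 fell (−0.40) among 24 genes of the G1/S transition and 0 of 16 genes of G2/M changed, as adjusted over the list alone. Among 16 daughter and early G1 genes, AMN1 (0.43) and the inhibitor SIC1 (0.29) rose and DSE2 fell (−0.43), with 3 risen and 1 fallen adjusted over the list alone. Of 10 histone genes, 0 changed, and 2 fell adjusted over the list alone. The lists of meiosis (15 tested), proteasome (33), phosphate starvation (16) and filamentous growth (14) had 0 risen and 0 fallen, also adjusted over the list alone. Of 31 lists, the pheromone response, the a-specific genes and the ribosomal proteins were the 3 called by camera with a preset correlation. With an estimated correlation 0 were called (adjusted p = 0.89), and by fry 0.

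The comparison of each exposure asked how far the response had gone by that time. With 1 array per exposure it has no test, and genes are given whose spots both passed a 2-fold ratio. At 3.5 min, 19 genes were higher and 2 lower, and 9 of the 19 belonged to the mating lists. The highest were AGA1 (2.68), MRPL25 (1.86), RPO21 (1.59), MFA1 (1.51), DAN1 (1.48) and AGA2 (1.44), the adhesion subunit of a-agglutinin. YNL120C (−1.17) and SBH1 (−1.05) were lower. At 7 min, AGA1 (1.65), MRPL25 (1.43) and FIT2 (1.03) were higher and SBH1 (−1.21) and YPR002C-A (−1.09, a name shared by several genes) lower. At 15 min, 27 genes were higher, 7 of them from the mating lists, and 54 lower. The highest were YGR109W-A (2.32), a Ty3 retrotransposon feature that carries several gene names, PRM1 (2.18), KAR4 (2.00), AGA1 (1.97), YMR304C-A (1.96) and YIL080W (1.92). The lowest were KKQ8 (−1.81), GMC1 (−1.61), MET30 (−1.58), PEX6 (−1.49), BMT6 (−1.48) and TVP38 (−1.43). At 30 min, AGA1 (1.51) was higher and 0 genes were lower. The split at 15 min depended on the scaling, with 53 higher and 10 lower after median centring of the array in place of loess. Counts at 7 min ranged from 2 to 24 over the settings that scale or centre each array and keep the 2-fold limit, and at 30 min from 1 to 13.

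The mating lists stood out most at 3.5 and 15 min. The median of the a-specific genes was 1.08, 0.13, 0.82 and 0.28 after 3.5, 7, 15 and 30 min, at percentiles 100, 95.1, 100 and 100 of random lists of equal size and brightness. The pheromone response list had medians of 0.24, 0.06, 0.33 and 0.07, at percentiles 100, 90.7, 100 and 97.8. Cytosolic ribosomal proteins had medians of 0.18, 0.02, 0.26 and −0.09, at percentiles 100, 43.4, 100 and 0.070. After median centring their 7 min median was at percentile 1.18 and their 30 min median at 0.010, so the order among equally bright genes at 7 min depended on the scaling. Histones were at 0.08, −0.12, −0.25 and −0.20, and the last of these was at percentile 0.050. Genes of hexose transport and galactose use were at −0.05, −0.02, 0.01 and −0.15, the last at percentile 0.080. In the deposited log ratios this last percentile was 31.7, and that of the pheromone response list at 30 min was 85.3. The a-specific genes at 7 min were at percentile 86.2 after median centring and 64.2 in the deposited log ratios. Over 31 lists and 4 arrays, 23 medians lay outside the central 95% of random lists, 17 above and 6 below. Of these 23, 15 stayed outside on the same side after median centring and 13 in the deposited log ratios. The random lists hold unrelated genes, while members of a list can vary together. The percentiles can therefore overstate how far a list stands out, and they are not p-values.

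**Figure D3:**
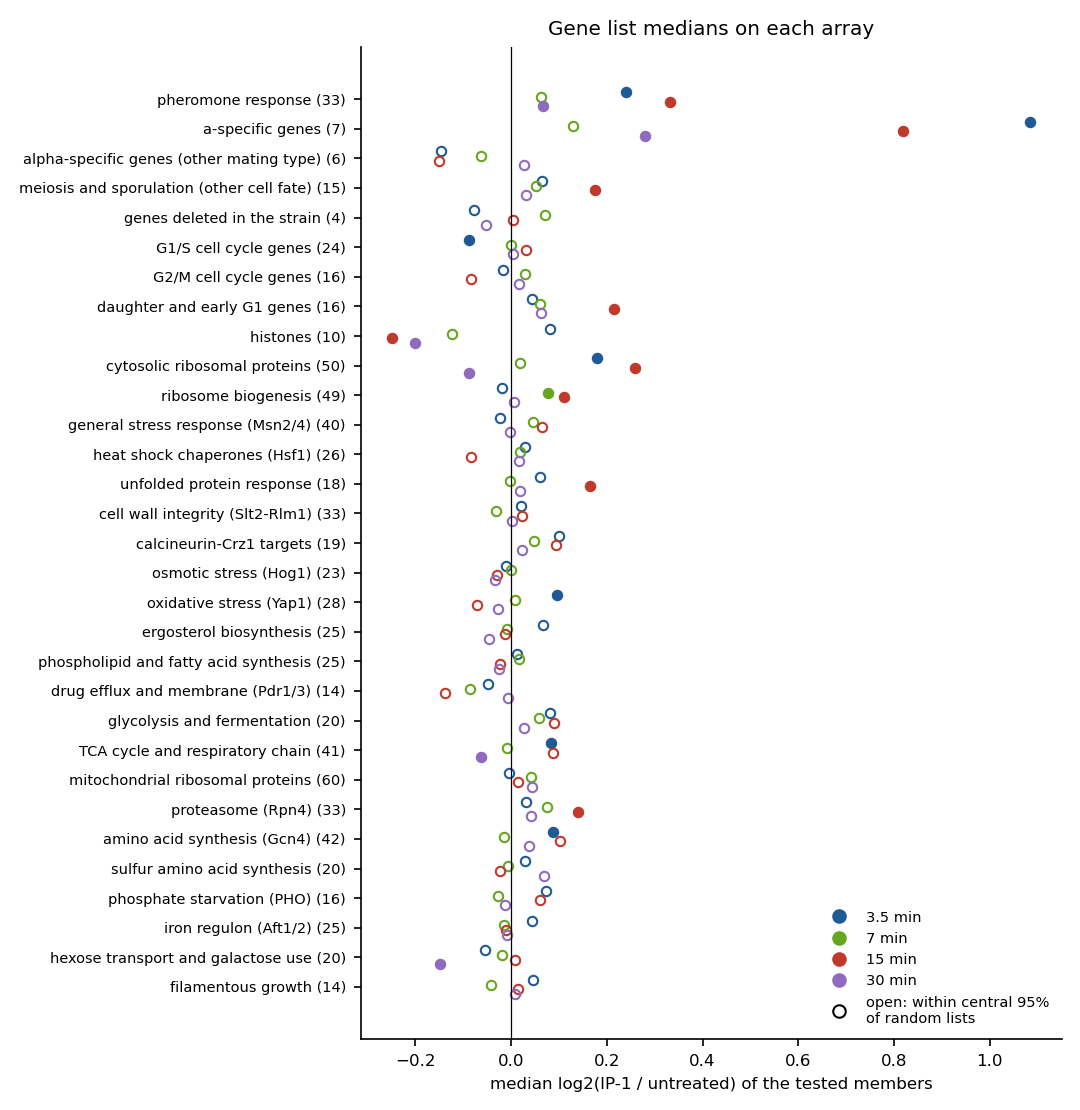
Median log2 ratio of IP-1 over untreated RNA of the tested members of 31 gene lists (number tested in brackets) on each of the 4 arrays; filled points lie outside the central 95% of random lists matched on size and brightness. The a-specific genes reach 1.08 at 3.5 min and 0.82 at 15 min, and the ribosomal proteins go from 0.26 at 15 min to −0.09 at 30 min.

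The comparison across exposures asked which transcripts changed steadily with time. In the slope on log2 of minutes, 0 genes passed in limma, with a smallest adjusted p of 1.00, and 61 of 6152 genes had an unadjusted p under 0.05, of which 30 had a rising slope. That share is smaller than the 0.05 expected if no gene had a trend, so the genes below are named by the rule only. The smallest p among rising genes belonged to ECT1, of phosphatidylethanolamine synthesis (0.06, 0.48, 0.69 and 0.91), BEM2, ELO1, GRS2 and MET18, and among falling genes to DPM1, CTF19, FIG2 (1.16, 0.53, 0.48 and 0.39), MRD1 and RIB1. The DPM1 value of 1.59 at 3.5 min came from spots at 2.94 and 0.24, with Cy3 not above background. Cy5 was not above background for ECT1 and RIB1 at 30 min and for BEM2 and MET18 at 3.5 min, nor was Cy3 for GRS2 at 30 min and MET18 at 15 and 30 min. Without the 15 min array 15 genes passed the slope test and without the 30 min array 30 did.

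Of the lists, cytosolic ribosomal proteins (camera, adjusted p = 7.7e-05), histones (adjusted p = 0.0049) and oxidative stress genes (adjusted p = 0.040) went down with time. None of these calls held in camera with an estimated correlation (adjusted p = 0.91). With the preset correlation, leaving out the 3.5 min array gave an adjusted p of 0.25 for ribosomal proteins and 0.64 for histones and oxidative stress genes. Without the 30 min array it was 0.22, 0.099 and 0.52, with the ribosomal proteins turned upward. Without the 15 min array it was 1.2e-10, 0.062 and 0.15. Over the settings tried it ran from 1.2e-10 to 0.91, from 0.0027 to 0.91 and from 0.016 to 0.97, and these lists were called in 15, 12 and 6 of 19 other settings, with the ribosomal proteins upward in 1 of the 15. The pheromone response list and the a-specific genes had a downward direction that was not called, each at adjusted p = 0.13 (0.91 with an estimated correlation). Both were called in 5 of 19 other settings, among them without the 7 min array (adjusted p of 0.0018 and 1.6e-05) and in the deposited log ratios (0.0055 and 0.0024). Without the 3.5 min array the direction of both was upward, at 0.64 and 0.53, and not called. The scanner columns number the arrays of 3.5, 7, 15 and 30 min as T2, T3, T4 and T1. If these numbers gave the order of time, an order tried only after the data had been seen, the ribosomal proteins would go up (adjusted p = 7.8e-07) and 0 genes would pass.

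The log2 ratios of different exposures resembled each other across genes. Pearson's r was highest between 7 and 15 min (0.602; Spearman's rho 0.584) and between 3.5 and 15 min (0.570; 0.503), and lowest between 15 and 30 min (0.305; 0.268). The other pairs had r of 0.532 for 7 and 30 min, 0.499 for 3.5 and 7 min and 0.404 for 3.5 and 30 min. These correlations run across genes, which are not independent replicates, and a constant dye effect raises all of them.

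**Figure D4:**
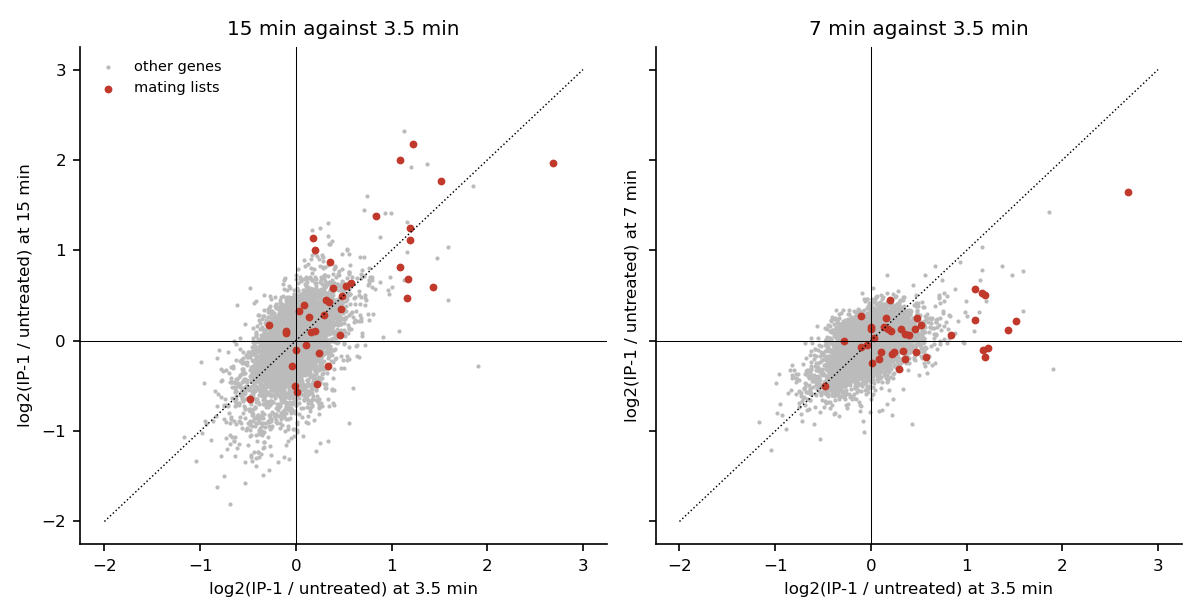
Log2 ratio of IP-1 over untreated RNA at 15 min (left) and 7 min (right) against 3.5 min for the tested genes, 1 point per gene, with the 40 tested members of the mating lists in red and equality dotted. Across all genes r was 0.570 and 0.499, and the a-specific median was 1.08 at 3.5 min and 0.13 at 7 min.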

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

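All tests in this part except the turning of array signs were chosen after the results were seen. Cytosolic ribosomal proteins stood out because their median lay on opposite sides of 0 at 2 exposures, at 0.26 after 15 min and −0.09 after 30 min, with a difference of 0.35 that was not tested. Genes of the TCA cycle and respiratory chain were picked out in the same way, with medians of 0.08 after 3.5 min and −0.06 after 30 min and a difference of 0.15, also not tested. Neither of these 2 medians lay outside the central 95% of random lists after median centring, at percentiles 96.7 and 4.69. Features named after Arabidopsis genes, which no comparison used, gave signal above the empty-spot limit in both dyes on all arrays for 18 of 32.

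The mating genes were higher at 3.5 and 15 min than at 7 and 30 min. An exchange of treated and untreated RNA on the 7 and 30 min arrays is argued against by the a-specific genes, of which 5 of 7 lay above 0 at 7 min and 7 of 7 at 30 min. Ratios narrower at 7 than at 3.5 min by 1 factor shared by all genes, dye effects included, are argued against: from covariances with the 15 min array the factor was 0.381 over 40 mating genes (95% bootstrap interval over genes, 0.103 to 0.592) and 0.987 over 6112 others, and by way of the 30 min array 0.66 (0.42 to 0.848) and 1.23. Such a factor may account for the values at 30 min, where the others' factor lay inside the interval in 4 of 4 comparisons (against 15 min by way of 3.5 min, 0.421, 0.148 to 0.654, others 0.365), and between 7 and 15 min it cannot be told apart from other causes, since the others' 0.573 lay inside the interval by way of 3.5 min (0.405, 0.0559 to 0.705) and their 1.15 above it by way of 30 min (0.712, 0.332 to 1.02). A treated sample mixed with untreated RNA, which would leave dye effects as they are, also cannot be told apart, as the 0.987 of the other genes holds an unknown share of dye effects, and a response that rises, falls and rises again stays open, with 1 array per exposure. Narrowing limited to genes of some brightness was not compared. The slope of the 7 and 30 min average on the 3.5 and 15 min average was 0.398 over the other genes. It lay inside the interval of the mating genes (0.343, 0.106 to 0.536), so this pooled comparison did not separate them.

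Many genes had a small ratio of steady sign on all arrays. In a separate fit of the same model that also held the features named after Arabidopsis genes, 43.8% of these were called (14 of 32), each of them lower, against 9.05% of the yeast features, and their medians were −0.35, −0.30, −0.25 and −0.32 after 3.5, 7, 15 and 30 min. These control features did not have to pass the background filter, unlike the yeast features, and 31 of 32 had a mean below 0. Whether RNA for these features was added, and in equal amounts, is not given in the sources used here. Unequal amounts could give such a common shift as well, so these calls do not decide on a dye effect of each probe. A dye or labelling effect of each probe is a candidate explanation for part of the 420 lower genes, and treatment is confounded with dye for all of them. Turning the signs of whole arrays gave 8 patterns, too few for a share under 0.125: the real signs called 548 genes, the highest other pattern 0, and 1 of the 8 patterns reached the real count.

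The LEU2 feature was among the brightest on every array although the strain lacks LEU2. Brightness set by the probe on the whole array is argued against by the ribosomal protein list, whose median brightness percentile was 80.8 (78.0 to 84.3) against 16.6 (7.28 to 50.1) for meiosis genes. Names displaced against the spots on the whole array are argued against by the a-specific median of 1.08 at 3.5 min, outside the −0.21 to 0.21 of random lists. This median does not bear on a wrong name of the LEU2 feature alone. Raw brightness percentiles of the other deleted genes ran from 64.8 to 80.6 for MET17, from 30.4 to 72.1 for HIS3 and from 9.42 to 22.8 for URA3. Other transcripts that bind this feature and a LEU2 copy in the cells cannot be told apart, since both give a bright feature in both dyes, as measured (percentile 99.9), and no biological explanation was tested.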

How the results depend on the processing

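The empty-spot limit, net intensities, the centred matrix and the column-number order were chosen after seeing the data, and the other settings before. Of the single-gene values, 643 kept direction and call, 57 were no longer called, 4 became called, 15 uncalled ones changed sign and 0 reversed. The 548 genes on the mean became 263 (50 higher, 213 lower) without background correction, 304 (78, 226) with median centring, 59 (7, 52) in the series matrix as deposited, 5 (4, 1) in that matrix centred, 930 with duplicate spots kept, and 10 to 575 with any 1 array left out (leave-one-out; 12 without 3.5 min, 10 without 7 min, 11 and 10 of them shared with the 548). The other settings gave 462 to 782. Between settings, 438 calls were shared with net intensities and 455 with print-tip loess, all with equal sign. The spot number as a replicate block gave 782 genes (212 higher, 570 lower), but the numbers pair nothing, since spot deviations of equal number correlated between arrays at −0.050 to 0.035.

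The slope called 0 genes in all settings except leave-one-out, which gave 0 to 30 (15 without 15 min and 30 without 30 min). The 3 lists called on the mean became 0 with an estimated correlation and 0 with fry. The 3 lists called on the slope became 0 with an estimated correlation, 0 with median centring, 6 without background correction, 0 to 6 in leave-one-out, 1 without replicate 2 (3 without replicate 1) and 1, turned upward, in column-number order.

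Of genes past 2-fold, the 21 at 3.5 min became 47 with plain subtraction, 38 with net intensities, 39 with these centred and 135 at 1.5-fold. The 5 at 7 min became 2 without background correction, 24 with plain subtraction, 3 with median centring, 1043 in the matrix as deposited, which is not centred, 17 in the matrix centred, 16 with net intensities, 18 with these centred and 63 at 1.5-fold. The 81 at 15 min (27 higher, 54 lower) became 460 at 1.5-fold, and the split became 53 and 10 with median centring, 45 and 14 in the matrix and 53 and 8 in the matrix centred. The 1 at 30 min became 5 without background correction, 13 with plain subtraction, 2 with median centring, 2 with no filter, 2 above the empty-spot limit, 6 in the matrix and 6 in it centred, 8 with net intensities and 8 with these centred, 37 at 1.5-fold and 4 on the mean of the spots. The cause was not tested for any of these. List medians outside the central range numbered 20 with median centring and 23 in the matrix, against 23, of which 15 and 13 stayed outside on the same side, and the mean correlation between arrays was 0.380 with median centring and 0.488 with print-tip loess, against 0.485. Signal over background, at 1.86 in Cy5 on the 30 min array, limits what dim genes can show.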

Other observations

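Features and genes in this part were chosen after their values were seen. Features of the Ty3 retrotransposon, whose transcription is known to respond to pheromone, had their highest values at 15 min. YGR109W-B was at 0.82, 0.29, 1.39 and 0.29 after 3.5, 7, 15 and 30 min (mean 0.70 ± 0.53, SD, n = 4; limma, adjusted p = 0.041), YIL082W at 1.00, 0.44, 1.42 and 0.42 (adjusted p = 0.021) and YIL082W-A at 0.25, 0.48, 1.24 and 0.42 (adjusted p = 0.040). YIL080W (adjusted p = 0.058) and YGR109W-A (adjusted p = 0.069) had their highest values of 1.92 and 2.32 at 15 min and did not pass. Apart from YGR109W-B, these features carry names of several genes, so they do not measure separate copies.

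Further genes passed 2-fold on both spots of 1 array. At 15 min NCW2, a GPI-anchored cell wall protein, was at 1.45, the chitin synthase CHS1, a member of the pheromone list, at 1.38, BAG7, a GTPase-activating protein for Rho1, at 1.60, the a-specific ASG7 at 1.13 and PST1 at −1.05, and at 3.5 min the surface protease YPS1 was at 1.08. NCW2, YPS1 and PST1 are members of the cell wall integrity list, and CHS1 and YPS1 also of the calcineurin list. These values come from 1 array each and have no test.

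Some locus names occur on a further feature with the suffix -r. Of these genes, CDC19 was at 0.56 and 0.54 and ENO1 at −0.53 and −0.74, while HXT2 was at −0.66 and −0.03 and PMP1 at −0.65 and 0.05. Over 83 such pairs the mean log2 ratios correlated across genes at 0.611, and of 27 pairs with a call 23 had the same sign and 7 had both called. The correlation is not one of independent replicates.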
